A study of Danio rerio with 6 samples.

How the data were processed

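The series holds 6 droplet-based single-cell RNA libraries from larval zebrafish, 1 for each condition. Unwounded larvae were taken at 3, 4 and 5 days post fertilization (dpf), and larvae burned on the tail fin with a handheld cautery at 3 dpf were taken at 6, 24 and 48 hours post burn (hpb), at the same 3 stages. Per the labels' protocols, the fish carried a green reporter driven by the neutrophil gene mpx and a red reporter driven by the macrophage gene mpeg1.1. Larvae were digested to single cells and cells positive for either colour were sorted together. The series design text gives the matching of burned to unwounded larvae by stage, and stage was used to pair the libraries. The replicate numbers are names only and carry no pairing of their own.

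The deposited values are UMI counts per gene and barcode, not normalized, in unfiltered matrices. Per the file headers, Cell Ranger 3.1.0 wrote the 2 libraries of 4 dpf and Cell Ranger 4 wrote the others, so the software version coincided with stage and not with burn. Per the labels' protocols the libraries were made with the 3' version 2 kit, but the 2 libraries of 4 dpf list 6794880 barcodes, the length of the version 3 list, and 3 of the others list 738601, 1559270 and 1772804, more than the version 2 list holds, so the kit is in doubt. The labels also give whole blood as the source, while their protocols describe digested larvae. The submitters' processing notes name Cell Ranger, Seurat, GRCz11 and danRer11; versions of the notes' tools and the gene annotation are not given in the sources used here. Features with the same symbol were added together, giving 36109 symbols. Total UMIs per library were between 27446860 and 95661155.

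Cells were called from the deposited counts. A barcode was kept if it held at least 500 UMIs and 200 genes, at most 10% mitochondrial UMIs, and differed from the profile of barcodes with at most 100 UMIs. That difference was tested by an own Monte Carlo multinomial test in the manner of EmptyDrops with 10000 draws and an adjusted p of at most 0.001. In simulated data the test called 0% of empty barcodes and 100% of barcodes with an even mix of cell and free RNA. The simulated cell and free RNA profiles were drawn independently of each other. Real empty barcodes hold RNA of the sorted cells, with neutrophil markers at 17060.5 to 55773.6 CPM. The simulation therefore does not show how the test performs on these libraries. Scrublet, run within scanpy 1.11.5, marked 3, 0 and 60 doublets in the unwounded libraries of 3, 4 and 5 dpf and 13, 3 and 104 in the burned libraries of 6, 24 and 48 hpb. At 4 dpf it marked 0% of the unwounded and 0.0885% of the burned cells, with thresholds of 0.591 and 0.479 against 0.262 to 0.312 in the other libraries, so doublet calling failed at that stage and doublets remain in both libraries.

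Counts were scaled to 10000 per cell and log-transformed, and 2000 variable genes, 30 principal components, 15 neighbours and Leiden resolution 1 gave the clusters, with no integration of libraries. A cluster was named from 16 marker sets fixed before the data were examined, by the highest mean z-score over at least 3 detected markers, unless its 10 leading genes contradicted the name. How leading genes were found was not fixed in advance, and 3 versions of that step were tried after cluster tables had been seen, the last of them after shares of response genes had been seen. The version used compares a cluster with other cells of the same libraries, in genes found in at least 10% of its cells, and asks for a leading marker before a non-myeloid name is given. This choice decides whether the cells that make up most of the neutrophil-like class at 48 hpb carry that name. The first version is reported among the alternatives.

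UMI counts were summed per library over neutrophil-like and over macrophage-like cells. The burn effect shared by the 3 stages was tested with edgeR 4.0.16 in R 4.3.3 (quasi-likelihood F-test, robust, TMM normalization, filterByExpr, Benjamini-Hochberg adjusted p below 0.05) with stage as a block, which leaves 2 residual degrees of freedom. The residual spread contains change of the burn effect with time as well as noise between libraries. A class by burn term was tested on the 12 sums of both classes. Gene lists were tested with camera of limma 3.58.1 with a preset correlation of 0.01 and then with an estimated correlation. In counts simulated from the real means for the neutrophil-like sums of 12429 genes, 71% of genes changed 2-fold and 100% of genes changed 4-fold were recovered, with 3.39% false calls. For the macrophage-like sums of 13018 genes these were 32%, 100% and 1.49%. The changed genes were drawn from those at or above the median expression. Every gene had the common dispersion, and the simulated burn effect did not change with time. These settings are easier than the data, so the real shares recovered may be lower.

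At a single stage there is 1 library per condition and no test. Log2 ratios of burned to unwounded TMM-scaled counts are given with an exact conditional binomial 95% interval that covers counting error only. In a simulation of the 6 hpb neutrophil-like ratio over 7245 genes the interval held the true value for 95.6% of genes. Where a library had 0 UMIs the ratio was set against a floor of 3 counts per library. A gene list is described by its median log2 ratio and the percentile of that median among 10000 random lists of the same size matched on mean expression in 20 bins. Random lists draw each gene on its own, so they do not copy the correlation within a list. List medians take members at any level against the empty barcodes. The 23 gene lists were fixed in advance.

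The genes named were chosen by a rule fixed in advance. From the common test it takes up to 10 genes in each direction that passed. Per stage it takes the 8 highest and 8 lowest ratios in neutrophil-like cells and the 5 highest and 5 lowest in macrophage-like cells, among genes with at least 50 UMIs over both libraries, an interval outside 1.5-fold and a level at least 2 times that of the empty barcodes. Mitochondrial and ribosomal genes, clone names and markers of other cell types are left out. It also takes the 2 members of each list with the largest ratio, and 8 response genes (il1b, cxcl8a, tnfa, tnfb, fosab, atf3, mmp9, hmox1a). Of the list members, those of lists outside the range of random lists at that stage were carried into the alternatives, and some of them are named here. That restriction was made after the values, and the number of them that turned under an alternative, were seen. A ratio with both libraries at 3 counts or fewer in an alternative was given no value there, a rule applied after such values were seen, and names of the zmp: kind were then treated as clone names. In the tests of explanations a bootstrap spread of list medians was added after the first outcome and left 2 explanations open that had first been excluded. It resamples the members of a list within a library pair and holds no spread between libraries.

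Shares of cells with a UMI were measured after thinning each cell to 500 UMIs, with exact (Clopper-Pearson) binomial 95% intervals, and were compared across stages with an exact permutation test, 3 against 3 libraries, whose smallest p is 0.1. That test does not use the pairing by stage, so differences between stages add to its spread. Alternatives fixed in advance were DESeq2 size factors, the DESeq2 1.42.0 Wald test, no filter on low counts, no stage block, leaving out each stage pair, at least 1000 UMIs per cell, no empty-barcode test, doublets kept, at most 5% mitochondrial UMIs, Leiden resolution 0.5, genes above the empty barcodes, total UMIs as the scale, and thinning to 500 or 1000 UMIs or not at all. Chosen after seeing the data were a fixed Scrublet score of 0.25, all clusters with macrophage as the best class, clusters led by heat shock genes left out, the first version of naming, and camera without each stage pair. Settings that change the cells also change the clusters and their names, so their values mix both.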

Results

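Myeloid cells of larval zebrafish were profiled after a tail fin burn to follow neutrophils and macrophages over the first 48 hours. The 3 unwounded libraries (3, 4 and 5 dpf) gave 1511, 7121 and 5992 cells and the 3 burned libraries (6, 24 and 48 hpb) gave 1507, 3387 and 5605. Total counts were 27446860, 73398848 and 95661155 UMIs in the unwounded and 29365412, 53478332 and 70638054 UMIs in the burned libraries. Neutrophil-like cells had a median of 7017, 8146 and 9723 UMIs in the unwounded libraries and 3233, 9654 and 8784 in the burned. Every condition had 1 library, so values at a single stage have no replicate check.

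Neutrophil-like cells, named from granule genes such as mpx, lyz and npsn, made up a larger share of the sorted cells in the burned library at each stage. At 6 hpb they were 43.9% of cells (95% interval 41.3 to 46.4) against 35.5% (33.1 to 37.9) in unwounded larvae. At 24 hpb they were 55.5% (53.8 to 57.2) against 25.01% (24.0 to 26.0), and at 48 hpb 36.7% (35.5 to 38.0) against 24.8% (23.7 to 25.9). Macrophage-like cells, named from genes such as mpeg1.1, marco and c1qa, were 41.2%, 29.997% and 27.9% in burned and 51.4%, 55.1% and 60.3% in unwounded libraries. Both colours were sorted into the same tube, so the sort gate sets these shares in part. Cells of other types count in them too, and at 48 hpb retina and lens-like cells were 24.3% of the burned and 1.52% of the unwounded library. At 6 hpb the neutrophil-like difference turned to -0.793 percentage points with at least 1000 UMIs per cell and to -9.23 without the empty-barcode test, and at 48 hpb it was -20.3 points under the first version of naming. Clusters kept out of the macrophage-like class after the data were seen would have made it 41.2%, 36.4% and 28.0% of burned and 54.5%, 65.9% and 61.3% of unwounded cells.

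**Figure D1:**
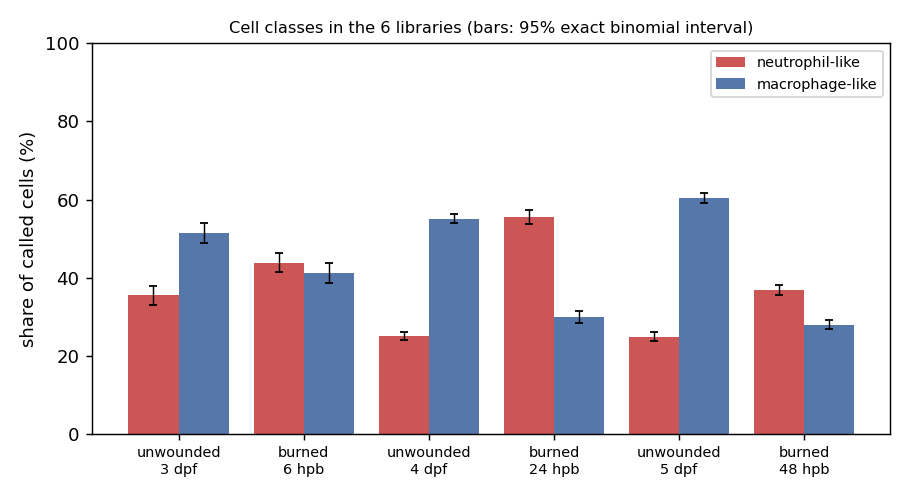
Share of called cells (percent) that were neutrophil-like or macrophage-like in each of the 6 libraries, with exact binomial 95% intervals of counting error. The neutrophil-like bar is higher in the burned library at each stage, with 55.5% at 24 hpb against 25.01% in unwounded larvae of 4 dpf.

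A change shared by all 3 stages was sought first in neutrophil-like cells. NF-κB feedback genes, which encode inhibitors and subunits of that inflammatory transcription factor, rose as a list with 20 of 22 members higher (camera adjusted p = 1.2e-06, and adjusted p = 0.517 with an estimated correlation). Endoplasmic reticulum stress genes rose with 24 of 31 higher (adjusted p = 7.7e-06) and ribosomal protein genes fell with 85 of 91 lower (adjusted p = 7.7e-16), each with an adjusted p of 0.517 with an estimated correlation. These 3 lists also passed without each stage pair in turn, but none of them stood outside the range of random lists at every stage. With the preset correlation, other splits of the libraries that part all 3 stage pairs gave 5 to 8 passing lists. The real labels gave 8, no more than the highest of these. Each of these splits swaps burned and unwounded in a stage pair, so it is not free of the burn. The counts therefore cannot tell whether the number of passing lists is particular to the burn. The NF-κB median was 0.09 at 6 hpb with 12 of 20 higher, the ribosomal medians were -0.26 and -0.06 at 6 and 24 hpb, and the endoplasmic reticulum stress median was -0.07 at 48 hpb with 19 of 30 lower, all inside that range. Lysosome and phagocytosis genes (0.000594), apoptosis and survival genes (0.0112), cytokines and chemokines (0.0133) and inflammation effectors (0.0365) rose, and neutrophil granule genes fell (0.0430), each with an adjusted p of 0.517 with an estimated correlation, and each of these calls needed particular pairs. Without the 3 dpf pair the adjusted p was 0.767 for cytokines, 0.767 for granule genes and 0.0725 for inflammation effectors. Without the 4 dpf pair it was 0.242 for apoptosis, 0.174 for granule genes and 0.0765 for inflammation effectors. Without the 5 dpf pair it was 0.0780 for lysosome, apoptosis and cytokine genes and 0.158 for inflammation effectors. Erythroid markers, which are globin and heme genes, rose in the same cells (adjusted p = 0.00210, and adjusted p = 0.933 with an estimated correlation) but fell without the 3 dpf pair (adjusted p = 6.1e-09).

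No single gene of neutrophil-like cells passed over all genes. Adjusted over the list alone, the NF-κB gene bcl3 was higher, as were eno1b and slc2a6 of the glycolysis list and the flagellin receptor genes tlr5a and tlr5b of the migration list. The edgeR quasi-likelihood test called 0 of 12429 genes, with 803 at an unadjusted p below 0.05, and the DESeq2 Wald test called 35. Without the 3, 4 or 5 dpf pair edgeR called 17, 62 or 156. The antigen presentation, immediate early, cell cycle, clock, complement, glycolysis, heat shock, interferon, lipid, migration, myeloid transcription factor, NADPH oxidase, oxidative phosphorylation, oxidative stress and repair lists did not pass (adjusted p of 0.0626 to 0.915). Some passed camera with a pair left out. Oxidative phosphorylation genes fell without the 3 dpf (0.0169) or 4 dpf pair (0.00593), and immediate early genes without the 3 dpf pair (0.0469). Cell cycle genes fell without the 4 dpf pair (0.00028) and complement genes without the 5 dpf pair (0.00887). Lipid genes rose without the 4 dpf (0.0400) or 5 dpf pair (0.0238). Glycolysis genes rose without the 4 dpf pair (0.00985) and heat shock genes without the 5 dpf pair (0.00019). The immediate early list had a median of -0.05 and a mean of 0.03, so these differ in sign.

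In macrophage-like cells the immediate early genes, which include the AP-1 family and respond quickly to many stimuli, fell with 39 of 45 lower (camera adjusted p = 1.8e-16, and adjusted p = 0.429 with an estimated correlation). Adjusted over the list alone 9 were lower, namely dusp2, egr1, fosab, gadd45ba, gadd45bb, ier2a, jdp2b, nr4a1 and nr4a3, and over all genes 0 were. Cytokines and chemokines fell with 21 of 27 lower (7.0e-08, and adjusted p = 0.753 with an estimated correlation), and ccl34b.1, csf3b and il11a were lower adjusted over the list alone. Ribosomal protein genes fell with 84 of 91 lower (1.5e-30, and adjusted p = 0.373 with an estimated correlation). These 3 lists also passed without each stage pair in turn, and the ribosomal median at 6 hpb (-0.39) lay inside the range of random lists. Other splits that part all 3 stage pairs gave 5 to 9 passing lists in macrophage-like cells, against 9 with the real labels. Macrophage markers fell beside them (adjusted p = 0.00614, and adjusted p = 0.821 with an estimated correlation), without the 3 dpf pair at an adjusted p of 0.347, and at 48 hpb they were higher (median 0.32, 17 of 21 higher).

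Other lists of macrophage-like cells passed only with particular pairs. Complement (0.00654), interferon response (0.0115), endoplasmic reticulum stress (0.0170), NF-κB feedback (0.0170) and cell cycle genes (0.0333) fell and lysosome genes rose (0.0333), each lost with an estimated correlation (adjusted p of 0.817 to 0.861). Without the 3 dpf pair the adjusted p was 0.0736 for complement, 0.0701 for interferon and 0.209 for NF-κB genes. Without the 4 dpf pair it was 0.0741 for endoplasmic reticulum stress, 0.129 for NF-κB and 0.524 for lysosome genes. Without the 5 dpf pair it was 0.673 for cell cycle, 0.319 for endoplasmic reticulum stress, 0.289 for interferon and 0.968 for lysosome genes. Adjusted over the list alone irf7, cd74a, cd83 and vegfaa were lower, the last 3 in lists that did not pass. The 14 other lists had adjusted p of 0.112 to 0.982. Of these, oxidative phosphorylation genes fell and passed camera without the 3 dpf pair (1.1e-05). Antigen presentation genes (0.00679) and inflammation effectors (0.0254) did so without the 5 dpf pair. The edgeR test called 0 of 13018 genes, with 835 at an unadjusted p below 0.05, and the DESeq2 Wald test called 34. Without the 3 dpf pair edgeR called 35, and without the 4 or 5 dpf pair 0.

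The classes were then compared for their burn effect. The only gene past the threshold among 14683 was zgc:158343, a gene without a name of its own that was chosen after its value was seen, whose burn effect in macrophage-like minus that in neutrophil-like cells was a log2 of -1.43 ± 0.15 (SE) in the edgeR test (adjusted p = 0.0282). At an unadjusted p below 0.05 there were 843 genes. Without the 3 dpf pair 146 genes were called, and without the 4 or 5 dpf pair 0. For il1b, the interleukin 1 beta gene, the burn effect was 0.93 higher (log2) in neutrophil-like than in macrophage-like cells (adjusted p = 0.732), with opposite signs at 3 of 3 stages, and for tnfb it was 0.98 higher (adjusted p = 0.198). Under the first version of naming the 48 hpb ratios of neutrophil-like cells turned to -0.44 for il1b and -0.80 for tnfb, the sign of macrophage-like cells, and thinned to 500 UMIs that of tnfb at 6 hpb lay below 0. The first version left a small remainder of the class at 48 hpb, 1858344 UMIs against 19777368 under the version used.

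At 6 hpb neutrophil-like cells had higher illr4, a lectin-like receptor gene (log2 ratio 3.08, interval 2.57 to 3.63), arg2, an arginase that breaks down arginine (1.56, 1.31 to 1.81), dck, a nucleoside kinase (1.78), and srp14, a signal recognition particle gene (1.62). Also higher were hist1h4l (3.39), fgl1 (2.27), fap (1.79) and stk39 (1.54). Lower were ryr3, a calcium release channel gene (-2.58, -3.02 to -2.16), gsto1, a glutathione transferase (-1.96), pla2g4ab, a phospholipase (-1.86), and dnmt3ab, a DNA methyltransferase (-1.91). The remaining lower genes were rbpms2b (-2.36), pigrl2.3 (-2.24), maco1a (-1.79) and pbxip1b (-1.79). Endoplasmic reticulum stress genes had a median of 0.56, above all 10000 random lists, with 25 of 28 members higher, among them the chaperone hyou1 (1.31) and the growth factor manf (1.26). Members of this list move together (estimated correlation 0.405 in the common test), which the random lists do not copy. Granule genes had a median of -0.46, with 14 of 17 lower, and neutrophil markers -0.43. Most of these markers are also in the granule list, so the second value largely repeats the first. The higher gene illr4 is in both. Glycolysis genes had a median of 0.23, with the glucose transporter slc2a6 at 1.52 and ldha at 1.24. Few of the higher genes of neutrophil-like cells stood at least 2 times above the empty barcodes. Among genes higher beyond 1.5-fold these were 35 of 328, 56 of 214 and 48 of 509 at 6, 24 and 48 hpb. Among genes lower beyond 1.5-fold they were 114 of 205, 43 of 122 and 68 of 276.

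Cytokine genes of neutrophil-like cells had a median of 0.82 at 6 hpb, with 16 of 17 higher, led by ccl34a.4 (3.07) and il6 (3.05). Both stood far below the empty barcodes (0.127 and 0.0948 times), and macrophage markers moved with them at a median of 1.16. The summed level of macrophage markers went the other way, at 2117 CPM in burned and 2796 CPM in unwounded neutrophil-like cells. Erythroid markers in these cells had a median of 2.74. Lysosome genes (median 0.30, marco 3.53, lgmn 2.497) and lipid genes (median 0.52, apoeb 2.30, fabp11a 1.90) were higher in the same cells and also lay below the empty barcodes. Without the empty-barcode test the ratios turned to -0.81 for ccl34a.4, -1.05 for marco, -0.43 for lgmn, -2.55 for apoeb and -1.38 for fabp11a, and the lysosome median turned to -0.46.

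At 24 hpb the protease inhibitor genes spink2.3, spink2.4 and spink2.2 were found in burned neutrophil-like cells (176, 128 and 79 UMIs) and not in unwounded ones (0 UMIs each), log2 ratios of at least 5.41, 4.95 and 4.25. Also higher were calr, a chaperone of the endoplasmic reticulum (1.74, 1.59 to 1.90), matk, a tyrosine kinase (1.67), capga, an actin capping gene (1.93), creb5a (1.91) and omgb (1.82). Lower were ifng1, interferon gamma (-1.46, -2.37 to -0.61), dusp8a, a phosphatase (-1.27), elovl6, a fatty acid elongase (-1.24), and gsto1 (-1.33). The other lower genes were znf576.1 (-1.40), vgll2a (-1.35), tjp1a (-1.32) and rev3l (-1.27). Endoplasmic reticulum stress genes had a median of 0.63 with 25 of 29 higher, and NF-κB feedback genes 0.55 with 18 of 21 higher, led by nfkb2 (1.48) and bcl3 (1.17). Heat shock genes had a median of 0.34, with hsp90aa1.2 at 2.00 and hsp70.2 at 1.59. Interferon genes had a median of 0.35, apoptosis genes 0.24 and cell cycle genes 0.17, the last of which turned to -0.0965 thinned to 500 UMIs. Macrophage markers in these cells had a median of -1.0001, cytokine genes -0.18 and erythroid markers -1.02.

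**Figure D2:**
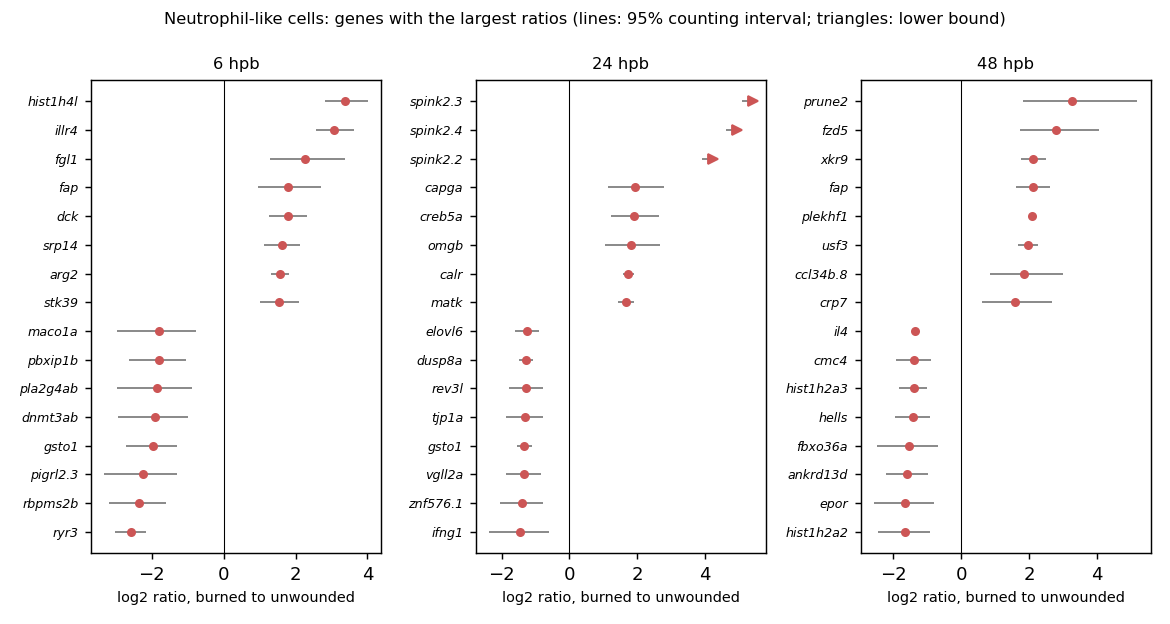
Log2 ratio of burned to unwounded TMM-scaled counts (horizontal axis) for the 8 highest and 8 lowest genes of neutrophil-like cells at each time, taken by the fixed rule. Points are ratios and lines are 95% counting intervals. Triangles are ratios against the floor of 3 counts for genes with 0 UMIs in the unwounded library, and are not the lower limits of their intervals. illr4 stands at 3.08 at 6 hpb and plekhf1 at 2.08 at 48 hpb.

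At 48 hpb neutrophil-like cells had higher plekhf1, an endosomal protein gene (2.08, 2.02 to 2.15, 661 against 156 TMM-scaled CPM), fap, a surface protease (2.104), fzd5, a Wnt receptor (2.79), and the chemokine gene ccl34b.8 (1.84). Also higher were prune2 (3.25), xkr9 (2.12), usf3 (1.97) and crp7 (1.58). Lower were il4, the interleukin 4 gene (-1.37, -1.42 to -1.31), epor, the erythropoietin receptor (-1.66), hells, a chromatin remodeller of dividing cells (-1.42), and the histone genes hist1h2a2 (-1.66) and hist1h2a3 (-1.40). The other lower genes were ankrd13d (-1.58), fbxo36a (-1.54) and cmc4 (-1.39). fap was higher at each of the 3 times (1.79, 1.52 and 2.104) without passing the common test (edgeR adjusted p = 0.165). Cell cycle genes had a median of -0.38 with 41 of 46 lower, oxidative phosphorylation genes -0.38 with 34 of 46 lower, and ribosomal protein genes -0.64 with 81 of 91 lower. NF-κB feedback genes had a median of 0.47, inflammation effectors 0.49 and lysosome genes 0.29. Macrophage markers in these cells had a median of 0.29 with 15 of 20 higher, and erythroid markers -1.36.

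The libraries of 5 dpf differed in which cells and which free RNA they held. A single cluster held 1982 of the 2059 neutrophil-like cells of 48 hpb and 187 of the 1488 of unwounded larvae, and the 2 libraries shared 16.3% of their neutrophil-like cells over clusters, against 76.0% of macrophage-like cells. Retina and lens markers had a median ratio of 2.21 in both classes, at 2143 against 496 CPM in neutrophil-like cells. Under the first version of naming, 1.37% of the burned library was neutrophil-like, and the cell cycle median turned to 2.08, the NF-κB median to -0.08 and that of inflammation effectors to -0.30. The ratios of xkr9 (-0.27), hells (0.21), hist1h2a2 (1.40) and hist1h2a3 (1.62) turned with them. Without the empty-barcode test the medians of inflammation effectors and lysosome genes turned to -0.10 and -0.17.

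In macrophage-like cells at 6 hpb, antigen presentation genes had a median of -1.09 and complement genes -1.59, with mhc2dab, a class II antigen gene (-3.52, -4.42 to -2.74), cd40, a costimulatory receptor (-1.71), c1qb (-2.86) and c1qa (-2.60) lower; the complement genes c1qa and c1qb are also macrophage markers. Higher were ifitm1, an interferon-induced membrane gene (4.45, 4.25 to 4.66), arf4b (5.50), kif7 (5.32), rbp7b (4.36) and eda (3.46). The other lower genes were phlda1 (-3.79), dicp1.1 (-3.13), plxnb1a (-2.93) and crfb15, a cytokine receptor gene (-2.91). Cytokine genes had a median of -0.53, with il12a at -2.70 and ccl35.1 at -2.41, and the iron exporter slc40a1 was at -2.07. Macrophage markers had a median of -1.04, neutrophil markers 0.51 (9 of 14 higher) and erythroid markers 2.32 in these cells. arf4b and kif7 rested on 2 UMIs each in the unwounded library.

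At 24 hpb macrophage-like cells had higher rab38b, a gene of lysosome-related organelles (2.80, 2.64 to 2.97), the small heat shock gene hspb1 (2.44), atp11a (2.27), pir (2.28) and fam69ab (2.28). Lower were rdh10b, a retinol dehydrogenase (-2.77, -3.04 to -2.51), the chemokine cxcl11.6 (-2.32), chst15 (-2.31), egr4 (-3.04, -6.12 to -1.12, 2 UMIs in burned cells) and hhipl1 (-2.51). Thinned to 500 UMIs egr4 and hhipl1 turned to 0.81 and 1.08. Cytokine genes had a median of -1.03 with 21 of 25 lower, led by il12a (-3.10) and csf3a (-2.08). Erythroid markers had a median of -0.54 over 4 genes in these cells, and neutrophil markers stood at 1789 against 3569 CPM (median log2 ratio -0.13). Lysosome genes had a median of 0.20, with gba at 0.91 and lgmn at 0.84, and this median turned to -0.13 at 5% mitochondrial UMIs and to -0.07 at Leiden resolution 0.5.

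At 48 hpb macrophage-like cells had macrophage markers at a median of 0.32 and erythroid markers at -1.94. Lysosome genes had a median of 0.46 with 35 of 36 higher, among them tfeb, the lysosomal transcription factor (1.04), and the protease ctsl.1 (0.99). Higher single genes were hspb1 (2.90), cd180, a Toll-like receptor homologue (2.42), gdpd3b (2.099), crfb15 (2.03) and loxl2b (5.91, 3.99 to 8.99, 2 UMIs in unwounded cells). Lower were stat1b (-4.16), mir132-2 (-3.49, 2 UMIs in burned cells), map3k7cl (-2.89), TM4SF19 (-2.45) and hist1h2a10 (-2.29), and thinned to 500 UMIs TM4SF19 turned to 0.62. Endoplasmic reticulum stress genes had a median of -0.22, with trib3 at -1.36 and chac1 at -1.09. Ribosomal protein genes had a median of -0.60 and oxidative phosphorylation genes -0.41. Immediate early genes had medians of -0.67, -0.46 and -0.46 at 6, 24 and 48 hpb, below the range of random lists at each time, with gadd45bb at -1.27, -0.98 and -1.40. In neutrophil-like cells of the same libraries the medians were 0.15, -0.07 and -0.17, the first of which turned to -0.0720 thinned to 500 UMIs. Over members at least 2 times the empty barcodes, the macrophage-like medians were -0.68, -0.15 and -0.02 (4, 9 and 14 genes). Those of 6 and 24 hpb lay inside the range of random lists of such genes.

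**Figure D3:**
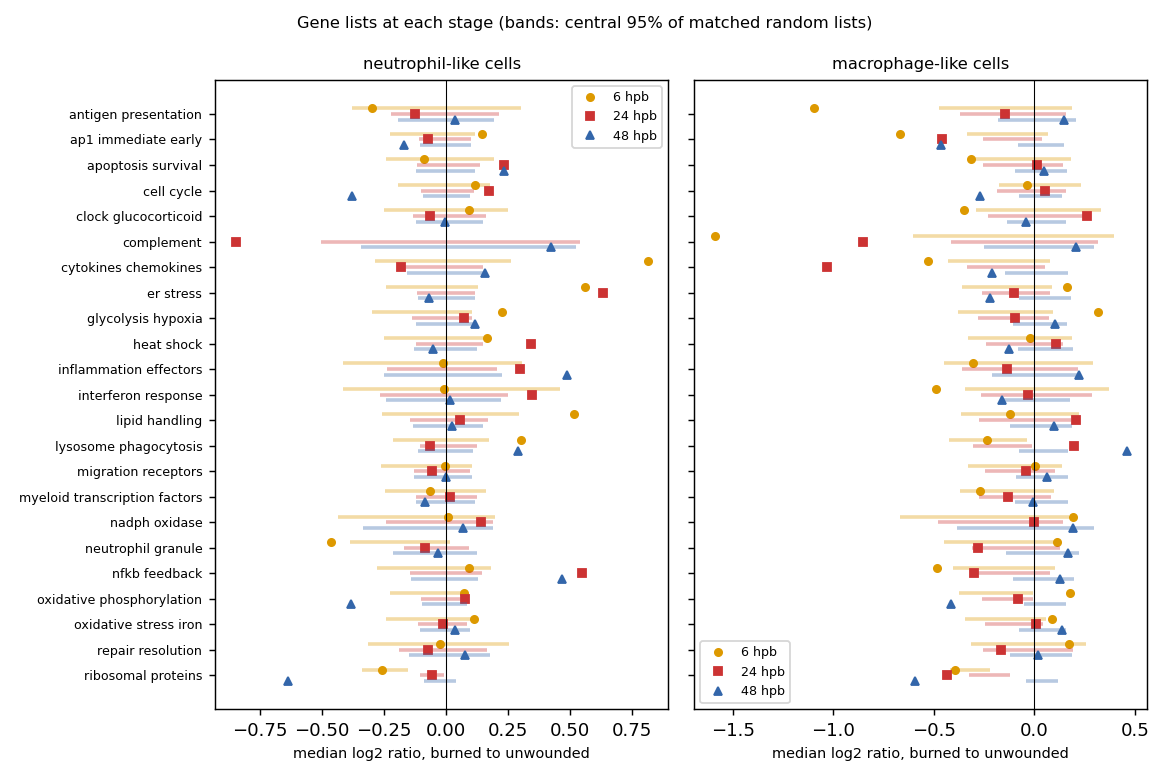
Median log2 ratio of burned to unwounded counts (horizontal axis) for each gene list (vertical axis) at 6, 24 and 48 hpb in both classes. Points are list medians and bands hold the central 95% of 10000 matched random lists; immediate early genes of macrophage-like cells lie at -0.67, -0.46 and -0.46.

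Heterogeneity among neutrophil-like cells was measured as the share of cells with a UMI of a response gene. il1b was found in 55.8%, 42.7% and 60.2% of neutrophil-like cells of burned and in 53.2%, 33.1% and 57.5% of those of unwounded larvae, higher at 3 of 3 stages. The means were 52.9% ± 9.11 and 47.9% ± 13.05 (SD, n = 3, exact permutation p = 0.6, adjusted p = 0.853 over 16 tests, without the pairing by stage). Non-myeloid cells had il1b in 4.17%, 15.4% and 13.2% of unwounded and 5.19%, 7.69% and 8.36% of burned libraries, at median depths of 11009, 1720, 2339, 9243, 2887 and 1938 UMIs. Without thinning the neutrophil-like shares were 82.1%, 86.9% and 89.8% in burned and 89.4%, 79.6% and 93.2% in unwounded libraries, so the order turned at 6 and 48 hpb. At 48 hpb the difference was also -0.462 points with doublets kept and -4.55 under the first version of naming. In macrophage-like cells il1b was found in 67.6%, 23.1% and 64.8% of burned and 78.7%, 47.7% and 68.9% of unwounded cells (exact permutation p = 0.5, adjusted p = 0.853). The share with fosab, an AP-1 subunit gene, was 5.75%, 8.14% and 8.94% in burned and 9.89%, 8.93% and 15.9% in unwounded neutrophil-like cells, against 5.19%, 33.3% and 9.83% of burned and 9.38%, 22.8% and 23.1% of unwounded non-myeloid cells. Without the clusters led by heat shock genes it was 4.60%, 4.41% and 8.82% in burned and 6.26%, 7.40% and 11.7% in unwounded neutrophil-like cells, so part of it lay in those clusters.

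The log2 ratios of the response genes in neutrophil-like cells at 6, 24 and 48 hpb were 0.13, 0.31 and 0.09 for il1b, 0.05, 0.65 and 0.59 for tnfb, 0.28, 0.41 and -0.01 for atf3, and -0.09, -0.31 and 0.21 for the gelatinase mmp9. cxcl8a (0.82, -2.18 and 0.80), tnfa (0.99, -0.38 and 2.09) and hmox1a (1.43, 0.14 and -0.42) lay at 0.0243 to 0.355 times the level of the empty barcodes. Without the empty-barcode test the 6 hpb ratios turned to -0.0769 for cxcl8a, 0.0351 for mmp9 and -1.44 for hmox1a, and that of mmp9 was 0.0154 with total UMIs. At 48 hpb cxcl8a turned under 5 alternatives (-0.0785 to -1.08) and mmp9 under 2, to -0.10 thinned to 500 UMIs and -1.12 under the first version of naming. In macrophage-like cells il1b had ratios of -0.44, -1.52 and -0.21 and tnfb -0.53, -0.33 and -0.70.

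**Figure D4:**
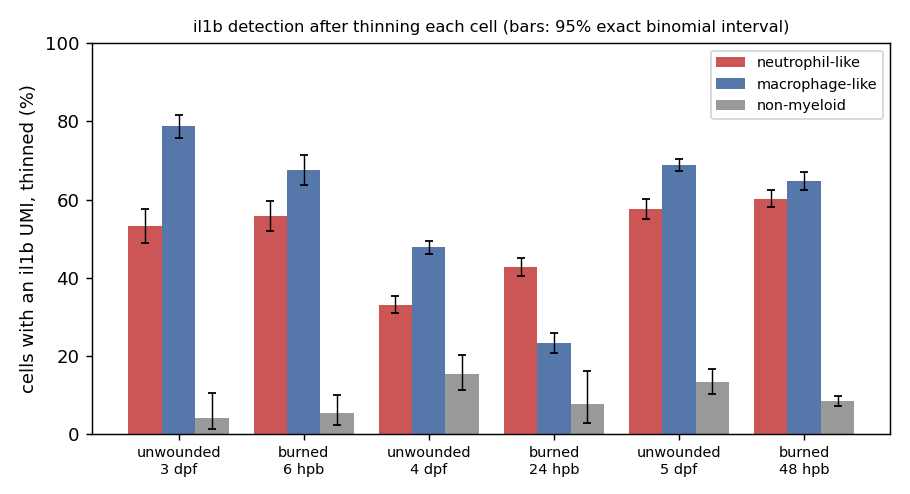
Share of cells (percent) with an il1b UMI after thinning to 500 UMIs, for neutrophil-like, macrophage-like and non-myeloid cells of the 6 libraries, with exact binomial 95% intervals of counting error. In macrophage-like cells the share is 23.1% at 24 hpb against 47.7% in unwounded larvae of 4 dpf.

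Response genes were found together in the same neutrophil-like cells. tnfb, a tumour necrosis factor gene, was found more often in cells with an il1b UMI in 6 of 6 libraries, with odds ratios of 2.40 to 4.77, as were atf3 (1.38 to 2.83), fosab (1.26 to 2.35) and mmp9 (1.08 to 2.19). For fosab this was 5 of 6 libraries thinned to 1000 UMIs (lowest odds ratio 0.795) and under the first version of naming (0.863), and for mmp9 5 of 6 with doublets kept (0.961). At 24 hpb tnfb was in 29.9% of cells with il1b and 8.17% of the others. The highest tnfb odds ratios, 4.57 and 4.77, were those of the 4 dpf libraries, where doublet calling failed, and with a fixed doublet score the highest was 3.97. tnfb was found in 20.3% to 42.4% of macrophage-like and 0% to 4.12% of non-myeloid cells. Odds ratios were above 1 in 5 libraries for cxcl8a, in 4 for hmox1a and in 3 of the 5 with any tnfa for that gene. Burned and unwounded libraries overlapped in these ratios, and no test was made over cells. Detection from free RNA was not set apart in these ratios, and no background share is given for atf3 and mmp9.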

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

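The test of handling, that of the shift at 24 hpb and the counts over other splits of the libraries were chosen only after the results were seen, as was the bootstrap spread used in the tests.

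The burn effect on zgc:158343 in macrophage-like minus that in neutrophil-like cells was a log2 of -1.43 (SE 0.15, edgeR adjusted p = 0.0282) and no call was left without the 4 or 5 dpf pair. The burn effect on il1b was 0.93 higher on the log2 scale in neutrophil-like than in macrophage-like cells, opposite at 3 of 3 stages, and did not pass the test of the difference (adjusted p = 0.732). That on tnfb was 0.98 higher, opposite at 3 of 3 stages, with an adjusted p of 0.198. Under the first version of naming neither gene was opposite at 48 hpb (-0.44 and -0.80 in neutrophil-like cells). These values rest on a small remainder of the class, 1858344 UMIs at 48 hpb against 19777368 under the version used. Among cells outside both classes, retina and lens-like cells were 24.3% of the cells at 48 hpb and 1.52% in unwounded larvae. Erythroid-like cells were 7.63% at 6 hpb and 3.44% in unwounded larvae, and neuron-like cells 5.32% at 48 hpb and 3.99%.

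Immediate early genes were lower in macrophage-like cells of burned larvae at 3 stages. Handling that acts with equal strength on both classes is argued against at 6 and 24 hpb, only for the library pair at each time. Neutrophil-like medians there were 0.15 (bootstrap interval over list members -0.06 to 0.31) and -0.07 (-0.18 to 0.21), against -0.67 and -0.46 in macrophage-like cells. These intervals hold no spread between libraries. At 48 hpb the neutrophil-like median was -0.17, below the range of random lists. Thinned to 500 UMIs the 6 hpb median turned to -0.0720, and the neutrophil-like list fell without the 3 dpf pair (camera adjusted p = 0.0469). Handling that acts more on macrophages was not tested and stays open. Free RNA stays open and may account for part or all of the lower immediate early values. Both outcomes set in advance for free RNA were met. Over members at least 2 times the empty barcodes the medians were -0.68, -0.15 and -0.0215, on 4, 9 and 14 genes. At 6 and 24 hpb they lay inside the range of random lists (-1.31 to 0.567 and -0.176 to 0.396), which is wide for so few genes. At 48 hpb the median lay just below that range (lower bound -0.0139). In the empty barcodes themselves the list was lower, with medians of -0.20 or below at each stage. That free RNA may itself come from macrophages, so the direction is open. With all clusters of macrophage as the best class the median at 24 hpb shifted by 0.00623 (paired bootstrap interval -0.0202 to 0.148) where 0.230 was needed, which argues against the choice of clusters there, while over all 3 stages (highest median -0.45) it cannot be told apart, because the setting barely moved the burned class at 6 and 48 hpb (621 and 1572 cells against 621 and 1565).

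Neutrophil-like cells of 48 hpb clustered apart from those of unwounded larvae of 5 dpf, with an overlap of 16.3%. Clustered without genes lower in both classes than in the empty barcodes, the overlap was 85.8%, against 77.5% for macrophage-like cells, so free RNA of other cell types is a candidate explanation. Retina and lens markers stood at 30720.5 CPM in the empty barcodes of that library and 10992 in those of unwounded larvae. With each cell thinned to 500 UMIs the overlap was 68.4%, short of the 89.6% of macrophage-like cells, and the part played by UMIs per cell stays open. The burn itself stays among the open explanations, as untested.

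Cytokine genes had a median of 0.82 in neutrophil-like cells at 6 hpb. The share of macrophage RNA that the median macrophage marker allows was 1.09% in unwounded and 6.96% in burned cells. The summed level of these markers went the other way, at 2796 CPM in unwounded and 2117 CPM in burned cells. After removal of that share the cytokine median was 0.21, with a bootstrap interval of -0.10 to 0.21. A member left at the floor of 3 counts in both libraries takes that same 0.21 from library scaling alone. The value therefore measures no remaining signal and cannot be set against the upper bound of random lists of 0.15. Macrophage RNA may account for much of the cytokine median, but how much cannot be told from this. Only 1 member stood at 2 times the empty barcodes or more, too few to decide on free RNA. A response of neutrophils to the burn stays open.

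The 6 libraries make 10 splits, too few for a share under 0.05. With a real count of 0 every split reaches it by construction, so the 10 splits for genes of neutrophil-like cells (real 0, highest other 0) and the 10 for macrophage-like cells (real 0, highest other 4) decide nothing. A count as large as the real one came from 7 splits for the difference between classes (real 1, highest other 34). They came from 4 splits for the lists of neutrophil-like cells (real 8, highest other 8) and from 4 for those of macrophage-like cells (real 9, highest other 9). Among splits that part all 3 stage pairs the highest other counts were 0, 0 and 0 genes and 8 and 9 lists. These splits swap burned and unwounded in 1 pair, so they are not free of the burn and their counts decide nothing about it. The 34 genes came from the split that sets unwounded 3 and 4 dpf with burned 24 hpb, and its counterpart. In these only the 3 dpf pair is parted, so with stage in the model that pair alone carries the contrast. That contrast is burned against unwounded at 3 dpf, so such a split is not free of the burn. Each split that parts 1 pair has a counterpart with the same fit, so the splits counted above are not all distinct.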

How the results depend on the processing

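The settings with a fixed doublet score, all macrophage-best clusters, no heat shock clusters, the first version of naming and camera without each pair were chosen only after the data were seen. Of 2735 ratios of named genes under alternatives 2148 stayed within their counting interval, 533 moved and 54 turned (128 of 4570 turned without the limits on list members and low counts, both set after outcomes were seen); of 1644 list medians 1472 stayed, 151 moved and 21 turned; of 147 shares of other response genes 99 stayed, 41 moved and 7 turned. The setting with all macrophage-best clusters leaves the neutrophil-like class unchanged, so the values of that class stayed there by construction and add to these totals. Where a value turned or moved the cause was not tested. At 500 UMIs per cell 37 ratios had both libraries at 3 counts or fewer and no value. Scaling to total UMIs moved the median of all genes to 0.10 and 0.18 in neutrophil-like cells at 6 and 48 hpb and to 0.18, 0.16 and 0.17 in macrophage-like cells at 6, 24 and 48 hpb, and thinning to 500 UMIs moved it to 0.16 in macrophage-like cells at 6 hpb.

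Genes called for the common burn effect in neutrophil-like cells went from 0 to 35 (DESeq2 Wald test), 315 (no filter on low counts), 34 (no empty-barcode test), 1 (mitochondrial share at most 5%), 1 (without heat shock clusters) and 17 to 156 (leaving out a pair). In macrophage-like cells they went from 0 to 34 (DESeq2 Wald test), 204 (no filter) and 0 to 35 (leaving out a pair). Genes that differed between classes went from 1 to between 0 and 146 (leaving out a pair). Lists past the threshold went from 8 and 9 to 0 and 0 with an estimated correlation.

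The difference in neutrophil-like share was -0.793 points at 6 hpb with at least 1000 UMIs, -9.23, 20.2 and 1.22 points at 6, 24 and 48 hpb without the empty-barcode test, 5.58 at 48 hpb with doublets kept and -20.3 at 48 hpb under the first naming. The difference in macrophage-like share was -1.21 at 6 hpb with at least 1000 UMIs. At 24 hpb it was -16.2 without the empty-barcode test, -18.5 with doublets kept, -22.7 with a fixed doublet score, -29.4 with all macrophage-best clusters and -13.7 under the first naming. At 48 hpb it was -28.4, -28.9 and -26.0 under the first, second and last of these and -30.0 at Leiden resolution 0.5. The difference in the share of neutrophil-like cells with il1b was -7.22 and -3.36 at 6 and 48 hpb without thinning, 6.06 at 24 hpb thinned to 1000 UMIs, 5.79 at 24 hpb with doublets kept and -4.55 at 48 hpb under the first naming.

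Without the empty-barcode test neutrophil-like ratios at 6 hpb turned for ccl34a.4 (-0.81), mafba (-1.05), marco (-1.05), lgmn (-0.43), fthl28 (-1.41), apoeb (-2.55), fabp11a (-1.38), cxcl8a (-0.0769), mmp9 (0.0351) and hmox1a (-1.44), and medians for lysosome (-0.46) and oxidative stress genes (-0.14). At 48 hpb mmp14b (-0.23), lgmn (-1.48) and cxcl8a (-0.81) turned, with cytokines (-0.29), inflammation effectors (-0.10) and lysosome genes (-0.17), and shares for cxcl8a at 48 hpb (-2.12), tnfa at 6 hpb (-0.363) and mmp9 at 6 hpb (1.65).

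Under the first naming neutrophil-like ratios at 48 hpb turned for xkr9 (-0.27), hist1h2a2 (1.40), hells (0.21), hist1h2a3 (1.62), cxcl19 (-1.15), rpa3 (0.75), top2a (2.08), birc2 (-0.0322), il1b (-0.44), cxcl8a (-0.90), tnfb (-0.80) and mmp9 (-1.12). Medians turned for cytokines (-0.96), inflammation effectors (-0.30), NF-κB (-0.0787), cell cycle (2.08) and apoptosis genes (-0.13), and shares for cxcl8a (-1.46) and tnfb (-0.578). All these values rest on a small remainder of the class at 48 hpb, 1858344 UMIs against 19777368 under the version used.

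Thinned to 500 UMIs, neutrophil-like values turned for immediate early genes at 6 hpb (-0.0720), bub1 (-0.12), fosab (0.0507), inflammation effectors (-0.15), oxidative phosphorylation (-0.0112) and cell cycle genes (-0.0965) at 24 hpb, and rpa3 (0.30) and mmp9 (-0.10) at 48 hpb. Macrophage-like values turned for nfkbib (0.35) and mmp9 (-0.0357) at 6 hpb, egr4 (0.81), hhipl1 (1.08), egr2b (0.59), msmo1 (-0.51) and lipid genes (-0.00324) at 24 hpb, and TM4SF19 (0.62) at 48 hpb.

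At 5% mitochondrial UMIs and at Leiden resolution 0.5, in that order, values turned for top2a in neutrophil-like cells at 48 hpb (0.87 and 0.88) and in macrophage-like cells for cfh (1.04 and 0.54), atf3 (0.0268 and 0.12), hmox1a (-0.0781 and -0.0856) and lysosome genes (-0.13 and -0.0738) at 24 hpb and mmp9 at 48 hpb (1.04 and 0.81), and at 5% alone for rps6kb1b at 24 hpb (0.19). In neutrophil-like cells at 48 hpb cxcl8a and the cytokine median turned with at least 1000 UMIs (-0.52 and -0.0656), a fixed doublet score (-0.0785 and -0.0835) and doublets kept (-1.08 and -0.14). With doublets kept mmp14b (-0.11), lgmn (-0.0950) and the cxcl8a share (-1.22) turned too, and without thinning that share (-4.20). With total UMIs mmp9 turned in neutrophil-like cells at 6 hpb (0.0154), and atf3 at 24 hpb (0.0335) and the heat shock median at 48 hpb (0.0353) in macrophage-like cells.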

Other observations

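Clusters outside both classes held other cells of the larva. Retina and lens-like cells, led by the cone opsin genes opn1mw1 and opn1sw1, were 1362 cells at 48 hpb and 91 in unwounded larvae of 5 dpf. Neuron-like cells, with elavl3 and stmn1b, were 298 and 239 cells in those libraries, and erythroid-like cells, led by globin genes such as hbae5 and hbbe2, were 115 at 6 hpb and 52 in unwounded larvae of 3 dpf. A cluster of 1099 cells led by the lipid genes apoeb and apoc1 and another of 694 cells led by ccl33.3 stayed without a name. Within the classes, a neutrophil-like cluster of 658 cells was led by the heat shock genes hsp70.2 and hsp70l, and clusters of 326 neutrophil-like and 784 macrophage-like cells were led by histone genes and mki67, a marker of dividing cells.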
